A study of Mus musculus with 11 samples.

How the data were processed

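RNA was sequenced from the small intestine of mice in 3 groups, in 11 libraries. The ND group (read as normal diet) had 3 libraries, and the HFD group (read as high-fat diet) and the group given 5 Substances Powder with Poria, a traditional Chinese preparation called FSP here, had 4 each. The sample labels say intestine, and the series design says small intestine. Groups and replicate numbers were taken from the sample titles. The labels describe FSP by the preparation alone and do not state its diet, and the series title speaks of obese mice. No label gives the age, sex, strain, dose, duration, the stretch of small intestine taken, or a batch. Nothing states that the libraries of a group came from separate animals beyond their being separate samples, so p-values measure the spread between these samples, which may be partly technical.

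Per the labels, total RNA was extracted with TRIzol and libraries were made with the VAHTS Universal V6 RNA-seq kit. The submitters' processing notes name fastp, HISAT2, HTSeq and R 3.2.0, and the genome build mm10. The annotation, the use of strand and the tool that computed expression are not given in the sources used here. The authors deposited expression as FPKM (fragments scaled to the length of the gene and the total of the library) for each library, and no read counts were used here. FPKM divides each library by its own total, so a class of RNA that takes a large share of a library lowers every other gene in it. The authors' FPKM summed to different totals per library, and the share of the 13 mitochondrially encoded protein genes in that sum ranged from 12.9% to 40.4%.

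The table of all libraries held 24250 gene symbols, of which 95.6% matched a RefSeq symbol. The single-library tables held identical values. Those of ND and HFD listed 685 further genes, each at 0, and lacked 641 genes that the table of all libraries gives as 0 in these groups, whereas those of FSP listed exactly the genes of that table. A different set of listed genes leaves open that FSP was tabulated apart from ND and HFD, which cannot be separated from the group.

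Depth was recovered from the values. For 658 genes with a single exon, low FPKM values were mostly whole multiples of what 1 fragment is worth in that library, which gave totals of 3.18e+07 fragments (HFD 1) to 3.82e+07 (FSP 4), with a ratio of 1.20 between the deepest and the shallowest. Of the values at or under 10 fragments in these genes, 73.4% to 77.7% per library lay within 0.05 of a whole fragment. Exon lengths of other genes depend on an annotation that is not stated, so whole counts were not rebuilt for all genes and no count model was used. A gene of 1 kb at 1 FPKM rests on about 32 fragments in the shallowest library, and depth limits mainly genes below that level.

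Values were tested as log2(FPKM + 1) with limma 3.58.1 in R 4.3.3 over the 10296 genes whose mean over the 11 libraries was at least 1 FPKM. The 3 groups entered a single fit with an intensity trend and no covariate. P-values were two-sided and adjusted by Benjamini-Hochberg within a comparison, with a threshold of 0.05. Log2 changes are on the log2(FPKM + 1) scale, which understates changes of genes at low levels. For 19 genes tied to the series title (gastric inhibitory polypeptide and lipid metabolism), the difference in mean log2(FPKM + 1) was also tested by a two-sided exact permutation test between the 2 groups compared. The smallest p that this test can give is 0.0286 for 4 against 3 libraries, and also for 4 against 4.

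A set of 40 gene lists for pathways and cell types was written down, and 38 had at least 5 tested members. They were tested with camera (limma) at a preset correlation between genes of 0.01, two-sided, with Benjamini-Hochberg adjustment over lists. Camera with the correlation estimated from the data, and fry, were alternatives. Camera compares a list with all other genes, so its direction can differ from the sign of a list's median. Some lists share members. The correlation between the HFD-against-ND and FSP-against-HFD changes was set beside 1000 simulations without effects that share the HFD libraries, and beside 6 splits of the HFD libraries between the comparisons. A position score per library was the mean log2(FPKM + 1) of a list of distal small intestine genes minus that of a list of proximal ones.

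The design, the tests, the lists and the rule for named genes were fixed before the data were examined. The rule took, per comparison, the 10 genes with the largest positive and the 10 with the largest negative log2 change among those past the threshold with an assigned symbol. It added the 19 focus genes, up to 4 members with the smallest p of each list described, and, for opposite changes, the 10 genes past the threshold in both comparisons with the smallest product of p-values. Unnamed gene models and immunoglobulin segments were only counted: 70 of the genes past the threshold in HFD against ND, 13 in FSP against HFD and 7 in FSP against ND. Genes named outside the rule are said to be so, and some genes the rule selects are not reported here. Locations are from GENCODE M21 (GRCm38, the assembly that mm10 denotes).

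Simulated data with the spread and size of these groups were used to test the calculation on 10296 genes. Of 100 genes changed by a log2 of 1, 71% were recovered for HFD against ND, 72% for FSP against HFD and 73% for FSP against ND. Of 100 changed by a log2 of 2, 97%, 95% and 96% were recovered. False calls numbered 13, 6 and 10, and no list was called. Genes were drawn independently of each other, so the simulation does not test list calls or false calls where genes are correlated.

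Alternatives planned in advance were other pseudocounts, filters, scalings and thresholds, pairs of groups fitted alone, library weights, the replicate number as a block, and leaving out each library. Alternatives added after the data were seen were a rescaling without mitochondrially encoded genes, the position score as a covariate, FSP 1 and FSP 4 left out together, library weights estimated gene by gene, and a factor for libraries numbered 1 and 2 against 3 and 4. Members of gene families with similar sequence (Oas1a and Oas1g, Reg3b and Reg3g, Saa1, Cyp4a10, H2-Q10) can share reads, and antisense genes such as Gata6os cannot be told from their partners without strand, so their values are uncertain. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was also used.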

Results

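Gene expression was measured by RNA sequencing in mouse small intestine on a normal diet (ND, n = 3), on a high-fat diet (HFD, n = 4) and in mice given 5 Substances Powder with Poria, a traditional Chinese herbal preparation (FSP, n = 4). The libraries held 3.18e+07 to 3.82e+07 fragments. Within groups, log2 values of pairs of libraries correlated across genes with r between 0.956 and 0.994, and the leading principal component held 48.3% of the variance. Mitochondrially encoded genes made up 40.4% of summed FPKM in HFD 1, 18.1% to 26.3% in the other HFD libraries, 16.3% to 22.2% in ND and 12.9% to 21.9% in FSP. The position score, high where distal genes exceed proximal ones, ran from 0.36 to 2.67 in ND, from −2.27 to −1.14 in HFD and from −0.81 to 1.23 in FSP. HFD lay below ND and below FSP (exact permutation p = 0.0286 for each, two-sided), and FSP was not separated from ND (exact permutation p = 0.257). The score leaves out the list of colon genes, which is described below. The mean log2(FPKM + 1) of 12 B and plasma cell genes was 1.28 to 1.37 in ND, 4.00, 3.92, 2.93 and 1.43 in HFD 1 to 4, and 4.58, 3.58, 1.33 and 1.85 in FSP 1 to 4. Adipocyte genes averaged 3.94 and 4.65 in FSP 1 and FSP 4 and at most 3.53 in the other libraries.

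**Figure D1:**
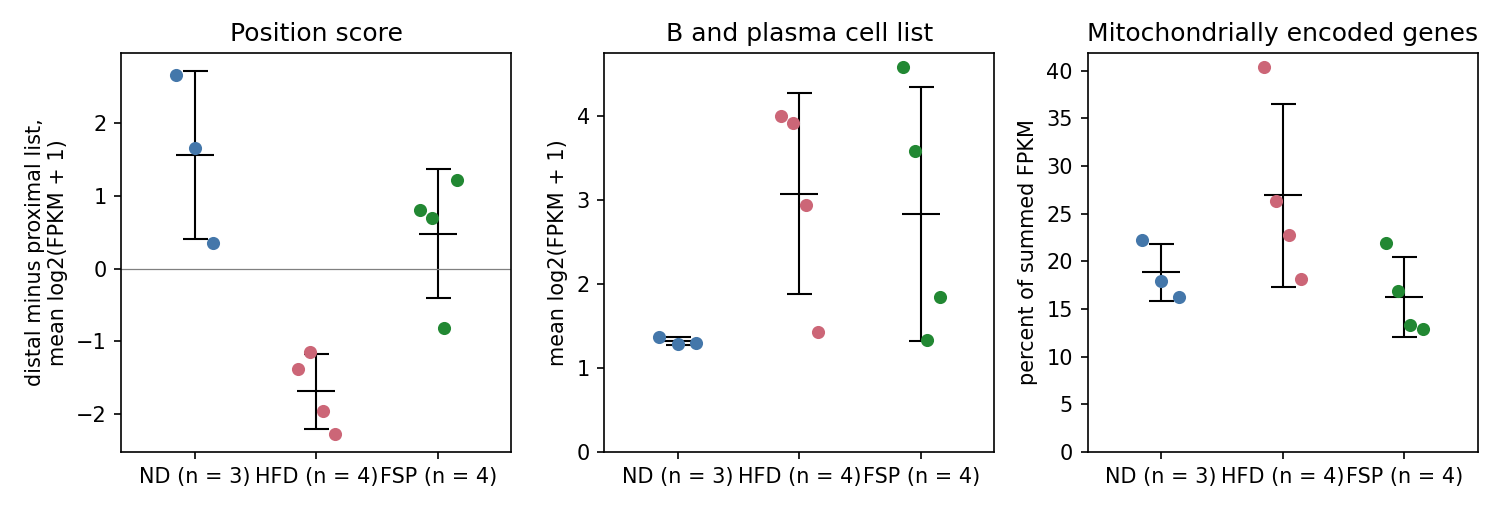
Position score (log2 units), mean log2(FPKM + 1) of B and plasma cell genes, and percent of summed FPKM from mitochondrially encoded genes, per library (points) with group mean and SD (bars). The position scores of the 4 HFD libraries, at most −1.14, lie below those of ND and FSP, and HFD 1 has the highest mitochondrial share at 40.4%.

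The comparison of HFD with ND asks what the high-fat diet was accompanied by in the small intestine. Gip, which encodes gastric inhibitory polypeptide, the incretin hormone of intestinal K cells, was higher in HFD, at 101 ± 12.8 FPKM (SD, n = 4) against 32.7 ± 14.8 (SD, n = 3), or 3.08-fold. Of 32 genes of fatty acid uptake and chylomicron assembly 10 rose, 1 fell and 21 did not pass (list adjusted p = 0.550 with an estimated correlation). Among the rises Apoa4, an apolipoprotein of chylomicrons, went from 1429.9 ± 1310.0 to 18326 ± 2512 FPKM. Pdk4, a kinase that spares glucose from oxidation, rose 2.63-fold. Of 25 cholesterol synthesis genes 23 fell (list adjusted p = 0.550 with an estimated correlation, and adjusted p = 0.00338 with fry). The farnesyl diphosphate synthase Fdps stood at 12.7 ± 2.47 FPKM against 44.5 ± 13.6. Fabp6, the ileal bile acid binding protein, stood at 2.86 ± 1.34 FPKM in HFD against 5640.0 ± 4801 in ND, and the epithelial oxidase Duox2 at 1.02 ± 1.20 against 46.3 ± 12.5.

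By limma with Benjamini-Hochberg adjustment, 552 of 10296 genes rose and 1557 fell in HFD against ND. The median log2 change over all tested genes was −0.21, and with median-ratio scaling, which brings that median to −0.02, 1114 genes rose and 964 fell. With quantile normalization 1125 rose and 1185 fell. The 10 largest rises were those of Apoa4 (log2 change 4.27), the ectonucleotidase Enpp3 (4.19), the sulfotransferase Sult6b2 (4.10), the intestinal folate transporter Slc46a1 (3.75), the alcohol dehydrogenase Adh1 (3.72), the adenosine deaminase Ada (3.61), Bbox1, the last enzyme of carnitine synthesis (3.52), Tm4sf4 (3.49), the esterase Aadac (3.47) and Reg1 (3.31). The 10 largest falls were those of Fabp6 (−9.66), the brush-border phospholipase Plb1 (−6.58), the acute-phase protein Saa1 (−5.94), the ileal bile acid transporter Slc10a2 (−5.77), Fam151a (−5.03), Tmigd1 (−4.90), the Duox2 maturation factor Duoxa2 (−4.89), the antimicrobial lectin Reg3g (−4.81), the glycosyltransferase Mgat4c (−4.79) and Duox2 (−4.68).

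Gip lies on chromosome 11 at 96024545 to 96030831 on the plus strand. Its log2 change in HFD against ND was 1.68 (SE 0.31, limma adjusted p = 0.00435), with every HFD library above every ND library (exact permutation p = 0.0286), and it stayed past the threshold without each single library. The other enteroendocrine genes went both ways. Of 19 measured members of the enteroendocrine list 3 rose, 4 fell and 12 did not pass, with the same 3 and 4 adjusted over the list alone. The stomach-type hormone gene Ghrl rose (1.56), the ileal and colonic peptide YY gene Pyy fell (−2.68), and the granule protein gene Scg2 fell (−1.53). Pcsk1, the prohormone convertase that processes such peptides, fell by 0.75 on the log2 scale (limma adjusted p = 0.0370). The list was not past its test (camera adjusted p = 0.765, and adjusted p = 0.962 with an estimated correlation), and its median of −0.49 has the opposite sign to camera's direction. The incretin receptor gene Gipr and the lipid receptor genes Ffar1, Ffar4 and Gpr119 averaged under the filter of 1 FPKM. At these low levels Gipr stood at 0.293 FPKM in HFD against 0.0798 in ND and Ffar4 at 0.402 against 1.53 (exact permutation p = 0.0286 for each, unadjusted).

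In the list of fatty acid uptake and chylomicron assembly, 10 of 32 measured genes rose, 1 fell and 21 did not pass (11 rose and 2 fell adjusted over the list alone). Its adjusted p was 2.51e-07 with camera and adjusted p = 0.550 with an estimated correlation. Besides Apoa4 the rises included the fatty acid activating enzymes Acsl3 (1.54) and Slc27a2 (1.68) and the pancreatic lipase cofactor Clps (1.98). Clps is also among the 4 measured pancreatic acinar genes, too few to test as a list and including a gene of the goblet cell list, whose mean log2(FPKM + 1) ran from 3.67 to 3.92 in ND and from 4.85 to 5.47 in HFD. The fatty acid binding protein Fabp1 rose by a log2 of 2.96 and the fatty acid translocase Cd36 by 1.23. With the position score as a covariate, added after the data were seen, these became −0.15 (SE 0.64) and −0.46 (SE 0.53), neither distinguished from 0, and Fabp1 is itself part of the score. Fabp2 and the lipid transfer protein Mttp changed by −0.22 and 0.49 and did not pass. Among 38 genes of fatty acid oxidation and PPAR-alpha targets, 11 rose, 2 fell and 25 did not pass (12 and 2 adjusted over the list alone; camera adjusted p = 1.67e-06, and adjusted p = 0.597 with an estimated correlation). Pdk4 (1.25) and the thioesterase Acot2 (1.12) rose and the pantetheinase Vnn1 fell (−2.22). Of 20 absorptive enterocyte genes 10 rose, 2 fell and 8 did not pass (11 and 2 adjusted over the list alone; adjusted p = 0.550 with an estimated correlation), with Rbp2, a retinol carrier (2.81), and the ecto-nucleotidase Nt5e (3.18) among the rises. That list shares 6 genes with the fatty acid uptake list. Cpt1a, Scd1, Fasn and the glucose transporter Slc5a1 did not pass, at −0.45, 0.66, −0.61 and −0.68.

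Cholesterol synthesis moved nearly as a block: 23 of 25 measured genes fell, 1 rose and 1 did not pass, with the same counts adjusted over the list alone (median −1.06, camera adjusted p = 5.50e-09, and adjusted p = 0.550 with an estimated correlation). With median-ratio scaling 21 fell and 1 rose. By fry the list had adjusted p = 0.00338. Fdps (−1.70) and the squalene epoxidase Sqle (−2.62) were among the falls. The member that rose was Insig1, a sterol-sensing regulator (0.82), named after its value was seen. Of 39 interferon response genes 23 fell, 16 did not pass and 0 rose by limma (25 fell adjusted over the list alone, and 12 with median-ratio scaling; camera adjusted p = 1.67e-06, and adjusted p = 0.550 with an estimated correlation). Ifi44 (−1.79), the antiviral oligoadenylate synthetases Oas1a (−1.96) and Oas1g (−1.98), and the double-stranded RNA sensor kinase Eif2ak2 (−0.92) were lower. By fry the interferon list had adjusted p = 0.0135.

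Antimicrobial and microbiota-responsive epithelial genes divided, with 13 of 28 lower, 6 higher and 9 not past (16 and 6 adjusted over the list alone). The list as a whole was not past camera (adjusted p = 0.510, and adjusted p = 0.962 with an estimated correlation). Duox2, Duoxa2, Saa1 and Reg3g fell, as did the inducible nitric oxide synthase Nos2 (−4.57) and Reg3b (−4.58), these last named after their values were seen. Reg3a rose (1.56). Of 29 genes of peptide and amino acid digestion and transport, 14 fell, 2 rose and 13 did not pass (14 and 3 adjusted over the list alone; camera adjusted p = 0.415, and adjusted p = 0.962 with an estimated correlation), with falls of the amino acid transporters Slc7a9 (−1.19), Slc1a1 (−2.96) and Slc6a19 (−0.96) and of the protease Mep1a (−3.28). Of 29 endoplasmic reticulum stress genes 15 fell, 1 rose and 13 did not pass (18 and 1 adjusted over the list alone), among the falls Manf (−0.96), Dnajb9 (−1.07) and Creld2 (−1.03). That list had camera adjusted p = 0.0618, and adjusted p = 0.958 with an estimated correlation.

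Genes that mark position along the gut moved with these groups. Of 16 distal small intestine genes 9 fell, 1 rose and 6 did not pass (10 and 1 adjusted over the list alone; median −1.01, camera adjusted p = 0.0142, and adjusted p = 0.550 with an estimated correlation), including the bile acid receptor Nr1h4 (−1.76), Mep1a, Fabp6 and the bile acid exporter Slc51a (−2.53). Of 11 proximal genes 6 rose, 1 fell and 4 did not pass (6 and 2 adjusted over the list alone; median 1.33, camera adjusted p = 2.08e-05, and adjusted p = 0.550 with an estimated correlation), with rises of Slc46a1, Adh6a and Fabp1 and a fall of the iron exporter Slc40a1 (−1.96). The distal list shares 6 members with the list of bile acid and sterol transport genes. By fry the distal list had adjusted p = 0.00570. Of 6 colon genes 3 fell, Saa1 and Cyp2c55 among them, and 3 did not pass (4 fell adjusted over the list alone). The colon list had camera adjusted p = 0.0195, adjusted p = 0.550 with an estimated correlation and adjusted p = 0.00186 with fry. B and plasma cell genes had a median of 1.77 with 0 of 12 members past limma, against 2109 of the 10296 tested genes. Their list had camera adjusted p = 3.93e-05, and adjusted p = 0.550 with an estimated correlation. With the position score as a covariate, an alternative chosen after the data were seen and one that overlaps with the groups, 1 gene, the receptor Gprc5a, was past the threshold in HFD against ND. Without ND 1 the counts were 264 higher and 613 lower and without ND 2 they were 289 and 560, and of 79 calls of genes named for this comparison 68 held without every single library, the others being those of Sult6b2, Reg1, Reg3g, Reg3b, Pcsk1, Cd36, Scg2, Guca2a, Ndufs8, Atp5j and Insig1.

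**Figure D2:**
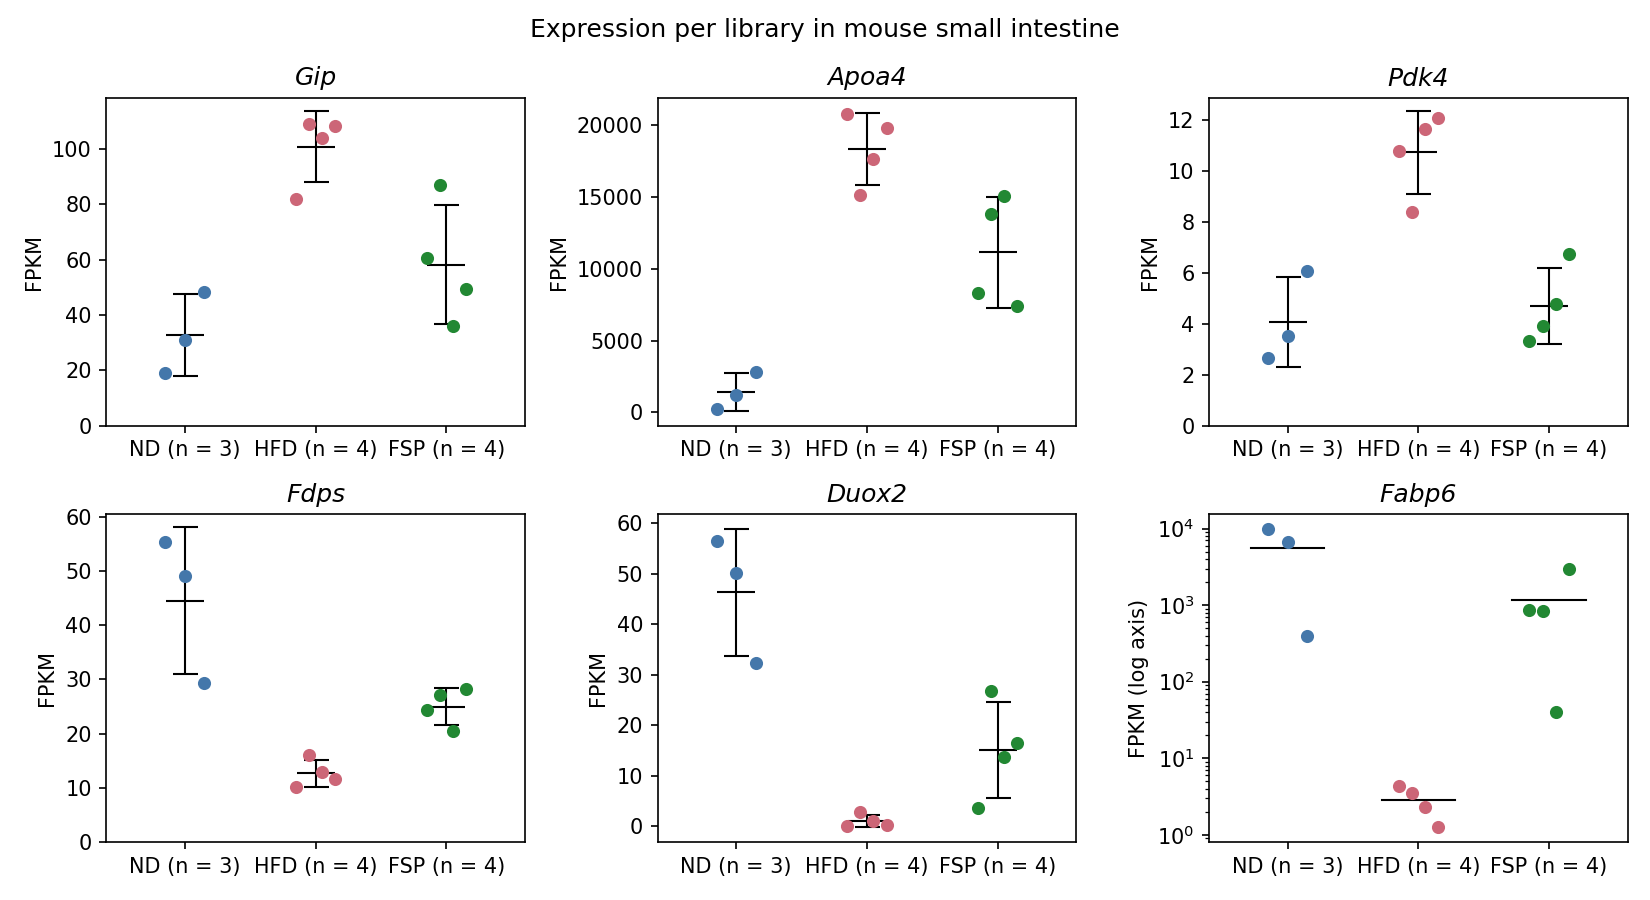
FPKM per library (points) of 6 genes in ND, HFD and FSP, with group mean and SD (bars); for Fabp6 the axis is logarithmic and the line is the mean. Gip averaged 32.7, 101 and 58.2 FPKM in ND, HFD and FSP, and Pdk4 averaged 4.07, 10.7 and 4.68 FPKM.

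The comparison of FSP with HFD asks what accompanied the herbal preparation. Pdk4 averaged 4.68 ± 1.49 FPKM (SD, n = 4) in FSP against 10.7 ± 1.63 (SD, n = 4) in HFD, close to the 4.07 ± 1.77 of ND. Fdps was higher in FSP, at 25 ± 3.49 against 12.7 ± 2.47 FPKM, or 1.97-fold, a call that ended with median-ratio scaling and without each of 7 single libraries (that of Pdk4 ended without each of 6). Fabp6 averaged 1172 ± 1247 FPKM in FSP (40.1 to 2953 between libraries, the call ending without FSP 4) against 2.86 ± 1.34 in HFD, and Duox2 15.2 ± 9.53 (the call ending without HFD 3 or FSP 4) against 1.02 ± 1.20. Gip averaged 58.2 ± 21.6 FPKM in FSP, 0.577 of the HFD mean, a log2 change of −0.84 (SE 0.29) that was not past the threshold (limma adjusted p = 0.140, exact permutation p = 0.0571).

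In FSP against HFD 291 genes rose and 94 fell by limma with Benjamini-Hochberg adjustment. The median change over all tested genes was 0.12, and the split moved to 195 and 188 with median-ratio scaling, 249 and 194 with quantile normalization, and 163 and 116 after rescaling without mitochondrially encoded genes, chosen after the data were seen. The largest rises were those of Fabp6 (log2 change 7.21), Plb1 (5.60), Fam151a (4.42), Mgat4c (3.33), Duox2 (2.91), Nos2 (2.85), Duoxa2 (2.81), Tmigd1 (2.73), the sialic acid lyase Npl (2.64) and the aminopeptidase Xpnpep2 (2.57). The largest falls were those of Reg1 (−3.43), the class Ib histocompatibility gene H2-Q10 (−3.01), Lypd8l (−2.69), the fatty acid hydroxylase Cyp4a10 (−2.61), Bbox1 (−2.45), Adh4 (−2.33), the calcium binding protein S100g (−2.26), the proton channel Otop3 (−2.26), the fetal serum protein Afp (−2.23) and Slc46a1 (−2.16).

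Over all tested genes 385 of 10296 were past limma's threshold in FSP against HFD. Among fatty acid oxidation and PPAR-alpha target genes 6 of 38 fell, 32 did not pass and 0 rose (10 fell and 1 rose adjusted over the list alone). The falls included Pdk4 (−1.07), Acot2 (−1.11) and the dehydrogenase Acadl (−0.82), and the calls of Pdk4 and Acadl ended with rescaling to equal totals. The list had camera adjusted p = 2.39e-11, and adjusted p = 0.815 with an estimated correlation. Of 25 cholesterol synthesis genes 7 rose, 18 did not pass and 0 fell (21 rose adjusted over the list alone, and 2 over all genes with median-ratio scaling; median 0.72, camera adjusted p = 5.92e-10, and adjusted p = 0.815 with an estimated correlation). Fdps (0.93) and the demethylase Cyp51 (1.15) were higher, and both calls ended with median-ratio scaling, with quantile normalization and with rescaling without mitochondrially encoded genes. Of 29 peptide and amino acid transport genes 8 rose and 21 did not pass (13 rose and 1 fell adjusted over the list alone; camera adjusted p = 0.00527, and adjusted p = 0.897 with an estimated correlation), with Slc7a9 (0.90), Slc6a19 (0.83), Slc3a1 (0.99) and the incretin-degrading peptidase Dpp4 (1.09) higher. The junction genes Cldn7 (0.72) and Epcam (0.71) rose and 24 of 26 in their list did not pass (the same 2 adjusted over the list alone; camera adjusted p = 0.00342, and adjusted p = 0.897 with an estimated correlation). In the fatty acid uptake and chylomicron list 1 of 32 fell, Slc27a2 (−1.16, a call that ended with rescaling to equal totals), and 31 did not pass (1 rose and 2 fell adjusted over the list alone). That list was not past camera (adjusted p = 0.168, and adjusted p = 0.897 with an estimated correlation). Apoa4, Cd36 and Fabp1 changed by −0.77, −1.02 and −1.33, and Fabp2 by 0.63. None of them passed limma's adjusted threshold (exact permutation p = 0.0286 for each, unadjusted). Of 28 antimicrobial and microbiota-responsive genes 3 rose, 2 fell and 23 did not pass (4 and 4 adjusted over the list alone). The antimicrobial list was not past camera (adjusted p = 0.549, and adjusted p = 0.897 with an estimated correlation).

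Mitochondrially encoded genes had a median of −0.73 with 0 of 13 members past limma over all genes and 7 lower adjusted over the list alone (camera adjusted p = 2.39e-11, and adjusted p = 0.681 with an estimated correlation). Their share of summed FPKM averaged 16.3% ± 4.18 (SD, n = 4) in FSP and 26.9% ± 9.62 (SD, n = 4) in HFD (exact permutation p = 0.0571). Of 16 distal small intestine genes 5 rose and 11 did not pass (9 rose adjusted over the list alone; camera adjusted p = 1.58e-05, and adjusted p = 0.681 with an estimated correlation). They were Fabp6, Mep1a (2.15), the cobalamin uptake gene Amn (0.96), Clec2h (0.86) and Slc51a (1.64), of which Amn and Clec2h were not past the threshold with median-ratio scaling. Of 11 proximal genes Slc46a1 and Reg1 fell and 9 did not pass (4 fell adjusted over the list alone; camera adjusted p = 0.000153, and adjusted p = 0.815 with an estimated correlation). Pyy, also expressed mainly in the distal gut, rose (2.17), a call that also ended with median-ratio scaling. The bile acid induced hormone gene Fgf15 averaged 9.33 ± 13.5 FPKM in FSP (3.26, 4.43, 0.203 and 29.4 in FSP 1 to 4, so FSP 4 carries the mean), 0.0648 ± 0.0586 in HFD and 6.20 ± 4.97 in ND. Its log2 change in FSP against HFD, 2.34, did not pass limma's threshold (limma adjusted p = 0.149, exact permutation p = 0.0286, unadjusted).

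The calls of this comparison depended on single libraries and on the fit, with 56 higher and 20 lower when only these 2 groups were fitted and 86 and 31 without a filter on low values. Numbers higher and lower were 34 and 14 without FSP 4, 52 and 16 without HFD 3, 116 and 42 without ND 2, 125 and 42 without FSP 1, 129 and 45 without HFD 1, 136 and 31 without HFD 4, 156 and 41 without FSP 2, 191 and 78 without ND 1, and 2 and 0 without FSP 1 and FSP 4 together (the interferon-response gene Ifit1bl1 and Marcksl1, named after their values were seen). Of 48 calls of genes named for this comparison, 17 held without every single library: Acot2, Plb1, Fam151a, Npl, Xpnpep2, H2-Q10, Bbox1, S100g, Slc7a9, Slc44a4, Bspry, Ceacam20, Slc52a3, Ext1, Tgfbi, Gata6os and Tuba4a. With the position score as a covariate, which overlaps with the groups, 0 genes were past limma's threshold: for Duox2, FSP against HFD, the change went from 2.91 (SE 0.51) to 2.39 (SE 0.84), a smaller value with a larger standard error.

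**Figure D3:**
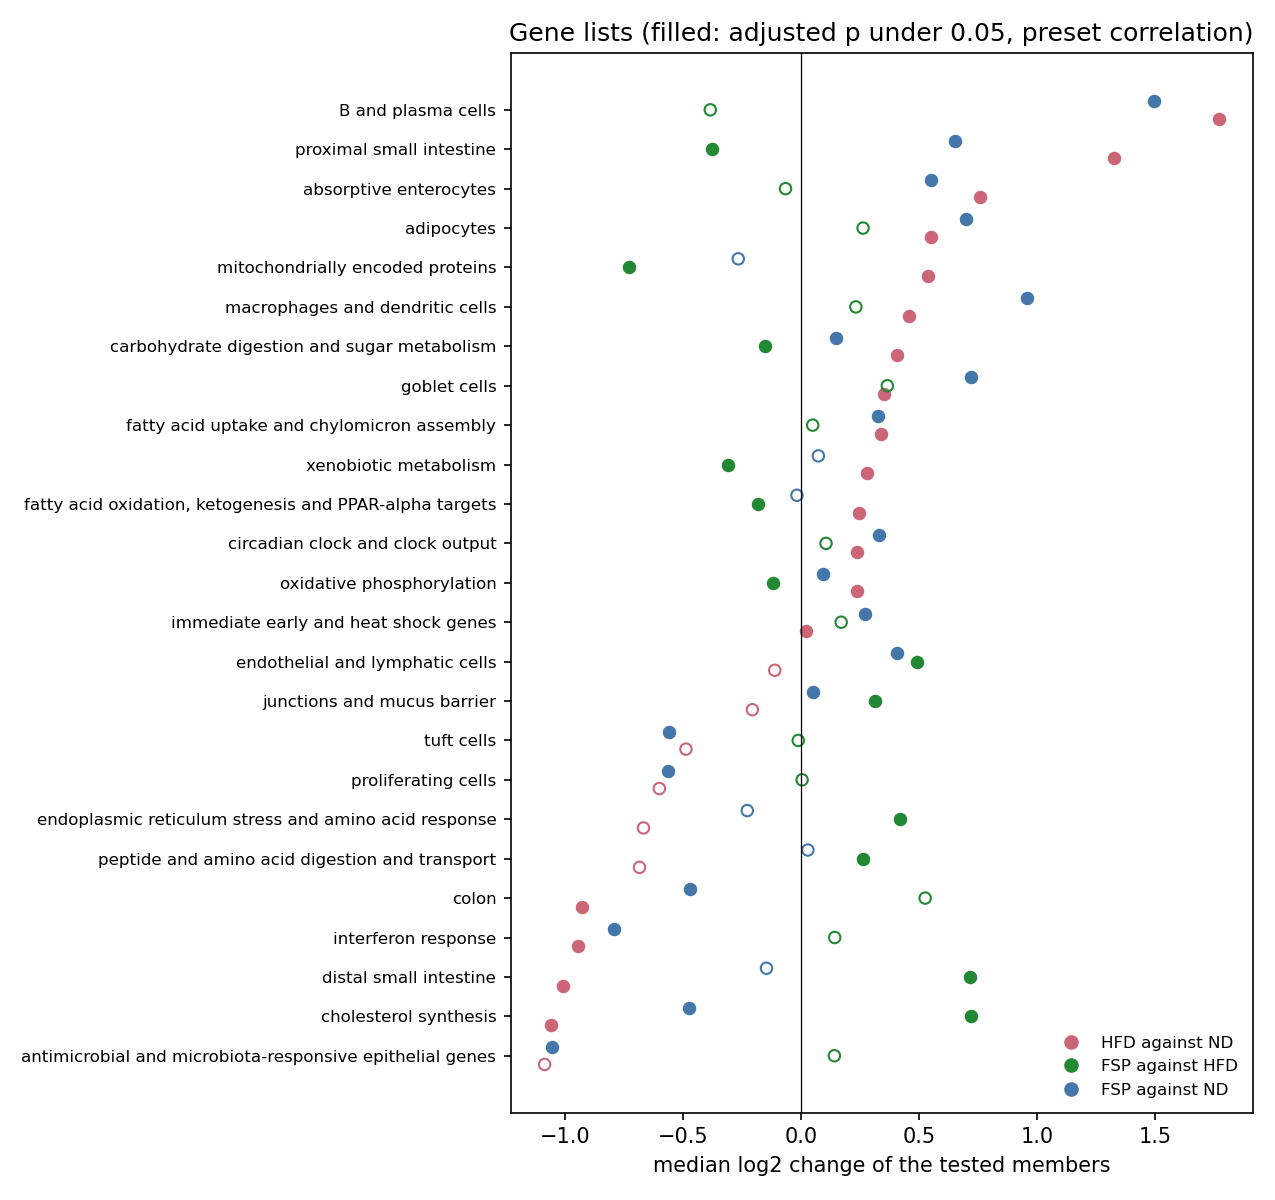
Median log2 change of the tested members of each gene list that was past the camera test with the preset correlation in at least 1 comparison, for the 3 comparisons (colours); filled points are past that test, open points are not. Cholesterol synthesis has a median of −1.06 in HFD against ND and 0.72 in FSP against HFD, and with an estimated correlation 0 lists were past the test.

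The changes in FSP against HFD mostly ran opposite to those in HFD against ND. The position score turned in the same way, averaging 1.56 in ND, −1.69 in HFD and 0.48 in FSP. A difference in the stretch sampled is therefore not told apart from diet or preparation here, and the labels do not state the diet of FSP. Of the 2109 genes past the threshold for the diet, 96.3% changed in the opposite direction in FSP against HFD, and 342 were past the threshold in both, 254 of them lower in HFD and higher in FSP, 88 the reverse, and 0 in the same direction, a division that the shared HFD libraries favour. Among the 10 with the smallest product of p-values, the thiamine pyrophosphate transporter Slc44a4 averaged 87.7 ± 17.5 FPKM in ND, 16.4 ± 2.92 in HFD and 51.4 ± 13.2 in FSP, and the riboflavin transporter Slc52a3 averaged 91.0 ± 6.35, 10.2 ± 2.99 and 51.4 ± 18.5. Bspry, the adhesion molecule Ceacam20, the heparan sulfate enzyme Ext1, the matrix protein Tgfbi, Npl and the tubulin Tuba4a showed the same pattern. Ltc4s, the leukotriene C4 synthase, ran the other way, at 3.89 ± 0.117, 40.3 ± 9.25 and 19.2 ± 5.07 FPKM, as did the antisense transcript Gata6os.

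Both comparisons use the HFD libraries, which makes their chance values opposite. Across the 10296 genes, which are not independent replicates, log2 changes correlated with r = −0.79, where simulations without effects gave a mean of −0.41 (95% between −0.94 and 0.54) and 193 of 1000 were as low. With the HFD libraries split between the comparisons r averaged −0.61 and lay between −0.77 and −0.43. The covariance was −0.166 against a simulated −0.0228, and 0 of 1000 simulations were as low. These simulations held no diet change either, and a real diet change widens the covariances that chance differences of FSP can give. The covariance therefore does not test whether the changes in FSP reversed those of the diet. The share of diet genes with the opposite sign averaged 65.2% in the simulations and 94.2% in the splits of the HFD libraries. Both were scored on the diet genes called in the real fit with all HFD libraries, and genes were not chosen anew. Neither share therefore includes the selection behind the observed 96.3% in the same way, and nothing is concluded from setting them beside it.

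**Figure D4:**
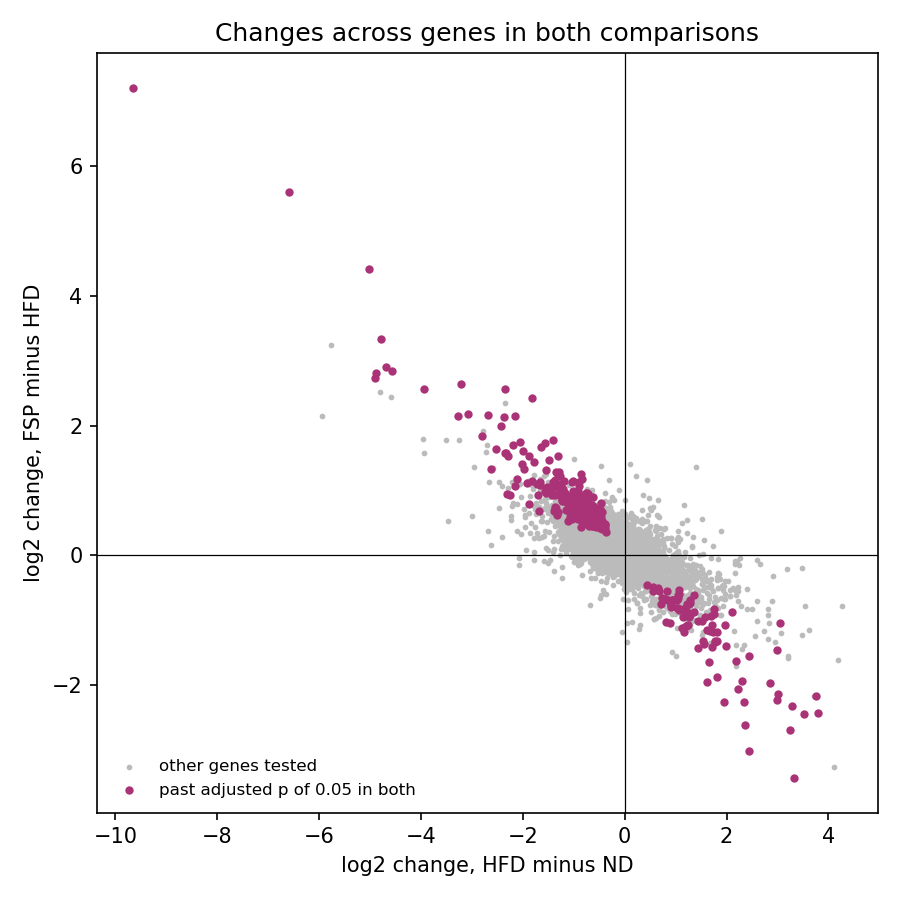
Log2 change in FSP against HFD (vertical) plotted against that in HFD against ND (horizontal) for 10296 genes; dark points are the 342 genes past the adjusted threshold in both. All 342 lie in the quadrants of opposite sign, and r across genes is −0.79, to which the shared HFD libraries contribute.

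FSP was also compared with ND, to describe what differed from the normal diet in mice given the preparation. Apoa4 averaged 11145 ± 3857 FPKM in FSP (SD, n = 4) against 1429.9 ± 1310.0 in ND (SD, n = 3; 245 to 2837 between libraries), or 7.79-fold, a call that ended without ND 2, HFD 3, FSP 1 or FSP 2. Tm4sf4, a tetraspan membrane protein, was 10.4-fold higher and the tight junction gene Cldn4 6.11-fold higher, both near their HFD levels. The xenobiotic hydroxylase Cyp2c55 was lower, at 9.51 ± 3.04 against 77.3 ± 7.18 FPKM, and so was the interferon-induced Ifi44, at 0.640 ± 0.346 against 4.47 ± 1.38. Gip averaged 58.2 ± 21.6 against 32.7 ± 14.8 FPKM and was not past the threshold (log2 change 0.84, limma adjusted p = 0.246, exact permutation p = 0.114).

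By limma with Benjamini-Hochberg adjustment 72 genes rose and 34 fell in FSP against ND. The median change over all tested genes was −0.07, and the numbers were 74 and 62 after rescaling without mitochondrially encoded genes, 126 and 66 with quantile normalization, 72 and 71 with a pseudocount of 5, and 25 and 33 without a filter. The largest rises were those of Apoa4 (3.49), Tm4sf4 (3.29), Nt5e (2.97), Jchain, the joining chain of secreted antibodies (2.76), Cldn4 (2.54), Gprc5a (2.53), Aadac (2.25), the vitamin C transporter Slc23a1 (2.22), the nucleoside transporter Slc28a2 (2.12) and Ly6m (2.08). The largest falls were those of Cyp2c55 (−2.95), AA467197 (−2.39), Ceacam10 (−2.30), Csta2 (−1.86), Ifi44 (−1.73), the neuropeptide neuromedin U gene Nmu (−1.62), the phospholipase Pla2g5 (−1.43), the membrane protein Stom (−1.37), Sgpp1 (−1.35) and Nr1h4 (−1.33).

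Of 20 absorptive enterocyte genes 4 rose in FSP against ND, Apoa4, Nt5e, Slc28a2 and Rbp2 (1.98), and 16 did not pass (11 rose adjusted over the list alone; camera adjusted p = 3.38e-12, and adjusted p = 0.397 with an estimated correlation). In the fatty acid uptake and chylomicron list Apoa4 and Acsl3 (1.27) rose and 30 did not pass (2 rose adjusted over the list alone; adjusted p = 0.498 with an estimated correlation). Of 39 interferon response genes Ifi44 fell and 38 did not pass (20 fell adjusted over the list alone; camera adjusted p = 9.62e-13, and adjusted p = 0.498 with an estimated correlation). Of 25 cholesterol synthesis genes 1 fell and 24 did not pass (8 fell adjusted over the list alone, and adjusted p = 0.549 with an estimated correlation). Of 6 colon genes Cyp2c55 fell and 5 did not pass (2 fell adjusted over the list alone). The colon list had camera adjusted p = 0.00160, adjusted p = 0.397 with an estimated correlation and adjusted p = 0.0243 with fry. Of 28 antimicrobial and microbiota-responsive genes 28 did not pass (3 rose and 10 fell adjusted over the list alone, median −1.05). The antimicrobial list had camera adjusted p = 0.0141, and adjusted p = 0.549 with an estimated correlation. Of 12 B and plasma cell genes Jchain rose and 11 did not pass (2 rose adjusted over the list alone, and adjusted p = 0.518 with an estimated correlation). Among adipocyte genes the lipid droplet gene Cidec rose (1.40), with 50.6 to 63.9 FPKM in the FSP libraries and FSP 1 the lowest, and 11 of 12 did not pass (the same 1 adjusted over the list alone; adjusted p = 0.518 with an estimated correlation). Numbers higher and lower were 11 and 2 without ND 2, 14 and 4 without ND 1, 24 and 9 without FSP 1, 27 and 11 without HFD 3, 108 and 93 without HFD 1, and 22 and 4 without FSP 1 and FSP 4. Of 26 calls of named genes 6 held without every single library, those of Tm4sf4, Cldn4, Gprc5a, Nt5e, Cyp2c55 and Ltc4s (2.00).

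Over the 19 focus genes and 3 comparisons, 23 of 57 exact permutation tests gave p under 0.05. With 3 or 4 libraries per group 0 stayed under 0.05 after Benjamini-Hochberg adjustment over the 57, the smallest adjusted value being 0.0708. Limma, adjusted over all genes, called 12, with Gipr, Ffar1, Ffar4 and Gpr119 under its filter and not tested.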

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

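Several tests here were chosen after the results were seen: those on Hox genes, on the relation of the position score within groups to Gip and to the 6 oxidase and antimicrobial genes, on epithelial genes, on other enteroendocrine genes, and with the position score as a covariate. The slopes on the score of genes outside the position lists and the splits of the libraries were chosen before.

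HFD libraries had higher proximal and lower distal small intestine genes than ND libraries, and a difference in the stretch sampled would give the same. Posterior minus anterior Hox genes, which record position, were lower in HFD than in ND by a mean log2 difference of −0.20 (exact permutation p = 0.0286, two-sided). That is the direction of a more proximal stretch in HFD. However, the difference averages all 24 listed Hox genes, of which only 6 were past the filter of 1 FPKM, and FSP (−0.23) lay near HFD (−0.29). Within groups, the slopes on the score of the 10269 genes outside the proximal and distal lists correlated with the HFD-against-ND changes. The size was 0.174, in the direction of a proximal shift, but 59.7% of 1000 random axes gave as much. The relation came from ND (r = −0.38 in ND, 0.04 in HFD and −0.03 in FSP, and −0.34 to −0.04 without single libraries), so this test does not decide. HFD does not overlap the other groups in the score, so a regional expression programme altered by diet or preparation is not told apart from sampling, and it was not tested.

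Reg3b, Reg3g, Duox2, Duoxa2, Nos2 and Saa1 were lower in HFD than in ND. Within groups their mean was related to the position score with r = 0.274 (exact permutation p = 0.425; 0.234 without the 2 libraries farthest from their group's mean score), which leaves a difference in stretch open. Fewer epithelial cells would lower epithelial genes by as much, but the median change of 12 keratin and adhesion genes was −0.21. Of these 4 were lower and 0 higher, the lowest being Tspan8 (−1.97). The 6 genes fell by 4.57 to 5.94, so epithelial content does not account for falls of that size. For Duox2, HFD against ND, the change with the score as a covariate went from −4.68 (SE 0.55) to −3.91 (SE 1.13, limma adjusted p = 0.249), and the call ended mainly because the standard error grew. A change in the microbiota, named in the series title, was not measured here.

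Gip was higher in HFD than in ND. Within groups it was related to the position score with r = −0.24 (exact permutation p = 0.593; −0.53 without the 2 libraries farthest from their group's mean score), which leaves a difference in stretch open. A larger total of enteroendocrine cells would raise their other genes, but 17 of these did not rise as a set, with a median change of −0.49. Ghrl (1.56) and Chga (0.60) were the 2 higher, and Pyy (−2.68), Nts (−1.29) and Scg2 (−1.53) the 3 lower. A more proximal stretch would also lower genes of the distal gut such as Pyy, so this median does not decide on the total. The number of K cells alone was not tested. For Gip, HFD against ND, the change with the score as a covariate went from 1.68 (SE 0.31) to 1.25 (SE 0.64, limma adjusted p = 0.376), a smaller value with a larger standard error. Induction of Gip by fat in the diet remains a reading these data cannot test.

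Each comparison was repeated over 35 ways of dividing its libraries. The real division was the only 1 that gave as many genes past the threshold for HFD against ND (2109, next highest 415) and for FSP against ND (106, next highest 41). For FSP against HFD 2 of the 35 gave at least the real 385, and the other, libraries 1 and 2 against 3 and 4, gave 543, so this test does not exclude chance for that count. That division is a structure shared by HFD and FSP, and every remaining division gave 0 genes by limma. With it as a factor, added after the data were seen, 469 genes were higher and 167 lower. The factor was picked because its division called many genes, and fitting it takes their spread out of the residuals. The larger count is therefore not read as support.

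Of 316 groups of values for named genes and lists, 26 (8.23%) had a single library standing apart, measured as its gap to the nearest of the others divided by the range, where about 1 in 20 would by chance. HFD 1 was lowest for Creld2 (0.834), Dpp4 (0.943), Ext1 (0.919), Gip (0.831), Manf (0.937), Pcsk1 (0.870), Scg2 (0.898), Slc7a9 (0.831), the fatty acid synthesis list (0.890) and the proliferating cell list (0.940). HFD 2 was highest for Ffar4 (0.838) and Slc10a2 (0.847). FSP 3 was highest for Acadl (0.842), Acsl3 (0.914), Sult6b2 (0.901) and the proximal list (0.844), and lowest for Cyp2c55 (0.853), Guca2a (0.871), Plb1 (0.886) and Tmigd1 (0.889). FSP 2 was highest for Clec2h (0.966) and Ghrl (0.961), FSP 4 for Gpr119 (0.966), Sgpp1 (0.846) and Slc1a1 (0.870), and FSP 1 was lowest for Slc5a1 (0.917).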

How the results depend on the processing

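The alternatives below were planned, except those said to be added after the data were seen, and the causes of the shifts were not tested. Counts of genes are higher and lower. In HFD against ND they were 552 and 1557, and became 1114 and 964 with median-ratio scaling, 1125 and 1185 with quantile normalization, 250 and 362 with an absolute log2 change of at least 1 required, and 292 and 399 with that and an unadjusted p. In FSP against HFD they were 291 and 94, and became 86 and 31 without a filter, 238 and 45 rescaled to equal totals, 195 and 188 with median-ratio scaling, 249 and 194 with quantile normalization, 56 and 20 with only these 2 groups fitted, 69 and 46 with the log2 minimum, and 104 and 78 with that and an unadjusted p. In FSP against ND they were 72 and 34, and became 72 and 71 with a pseudocount of 5, 25 and 33 without a filter, 56 and 20 rescaled to equal totals, 126 and 66 with quantile normalization, 42 and 29 with only these 2 groups fitted, 48 and 17 with the log2 minimum, and 120 and 94 with that and an unadjusted p. Of the added alternatives, rescaling without mitochondrially encoded genes gave 163 and 116 in FSP against HFD and 74 and 62 in FSP against ND. The factor for libraries 1 and 2 against 3 and 4 gave 469 and 167, and 109 and 64, in these comparisons. It was picked because its division called many genes, so these counts are not read as support. Leaving out FSP 1 and FSP 4 gave 2 and 0, and 22 and 4. The position score as a covariate, also added, gave 1 and 0, 0 and 0, and 26 and 8 by limma in the 3 comparisons, and gave −0.24 (SE 1.91) for Sult6b2, −0.46 (SE 0.53) for Cd36 and −0.15 (SE 0.64) for Fabp1, a member of the score, in HFD against ND, with the sign opposite to the main one but none distinguished from 0. Library weights could not be fitted as planned: limma's default estimate did not converge and put weights of 147 on ND 2 and 104 on HFD 3. Weights estimated gene by gene, added, gave 11.1 and 10.2 to these libraries and called 2028 and 5189, 1187 and 405, and 458 and 610, which is not read as support. With the replicate number as a block the counts were 651 and 1706, 240 and 97, and 54 and 23, though equally numbered libraries were not related throughout (r from −0.10 to 0.45, highest in FSP against HFD). Lists past the threshold were 18, 12 and 19, with an estimated correlation 0, 0 and 0 by camera, and with fry 4, 1 and 1. By fry these were cholesterol synthesis (adjusted p = 0.00338), interferon response (0.0135), distal small intestine (0.00570) and colon (0.00186) in HFD against ND. In FSP against HFD it was the distal list (fry adjusted p = 0.0305), and in FSP against ND the colon list (fry adjusted p = 0.0243). Unlike camera, fry does not compare a list with other genes. The correlation of the diet and preparation changes went from −0.79 to −0.61 with the HFD libraries split, and their covariance from −0.166 to −0.260 with a pseudocount of 0.1 and −0.216 with a minimum of 5 FPKM. Focus gene tests under 0.05 were 23 of 57 by exact permutation, unadjusted. By limma, adjusted over all genes, they were 12, with Gipr, Ffar1, Ffar4 and Gpr119 under the filter and not tested. Leaving out 1 library gave 264 to 635 higher and 560 to 2043 lower in HFD against ND (ND 1 264 and 613, ND 2 289 and 560). It gave 34 to 348 and 14 to 123 in FSP against HFD (FSP 4 34 and 14, HFD 3 52 and 16, ND 2 116 and 42, FSP 1 125 and 42, HFD 1 129 and 45, HFD 4 136 and 31, FSP 2 156 and 41, ND 1 191 and 78), and 11 to 108 and 2 to 93 in FSP against ND (ND 2 11 and 2, ND 1 14 and 4, FSP 1 24 and 9, HFD 3 27 and 11, HFD 1 108 and 93). The correlation ran from −0.82 to −0.71, the covariance from −0.201 to −0.142, the opposite share from 94.2% to 98.1%, and lists past the threshold from 16 to 20, 10 to 19 and 16 to 22. Focus gene tests under 0.05 by exact permutation ran from 5 to 21. Each of the 23 tests was at the smallest p, 0.0286, so its groups did not overlap, and leaving out a library cannot make them overlap. Some of the smaller comparisons cannot reach p under 0.05. With 4 against 3 libraries another division can give as large a difference, which also lifts p above 0.05. The drop therefore does not show dependence on single libraries. In FSP against HFD camera's direction turned for the interferon list without FSP 2 (median 0.054, range 0.054 to 0.34 over the libraries) and for the T and intraepithelial lymphocyte list without FSP 3 (median 0.33, range −0.063 to 0.33).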

Other observations

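The observations here lie outside the questions of lipid metabolism and Gip, and those on libraries 1 and 2 against 3 and 4 were made after the results were seen. Genes of xenobiotic metabolism moved in both directions in HFD against ND: 12 of 51 rose, 4 fell and 35 did not pass (13 and 5 adjusted over the list alone), with camera adjusted p = 1.55e-06, and adjusted p = 0.640 with an estimated correlation. The glutathione transferase Gsta1 (2.74) and Adh4 (3.29) rose, and Cyp2c55 (−3.47) and the efflux pump Abcg2 (−1.69) fell. Of 59 genes of oxidative phosphorylation 12 rose, 47 did not pass and 0 fell by limma (12 adjusted over the list alone; median 0.24, adjusted p = 0.550 with an estimated correlation), among them Ndufs8 (0.51) and Atp5j (0.62). Of 17 circadian clock genes 4 rose, 1 fell and 12 did not pass (4 and 3 adjusted over the list alone; adjusted p = 0.550 with an estimated correlation). The clock output gene Dbp rose in HFD against ND (1.46) and in FSP against ND (1.14), and the labels give no time of day.

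B cell transcripts varied widely between the libraries of HFD and between those of FSP, and little in ND. Cd79a, a subunit of the B cell receptor, stood at 99.3, 59.3, 22.8 and 1.31 FPKM in HFD 1 to 4, at 95.3, 44.8, 0.733 and 4.07 in FSP 1 to 4, and at 0.752 to 1.47 in ND. Dividing the HFD and FSP libraries into those numbered 1 and 2 and those numbered 3 and 4, 223 genes were higher and 320 lower in 1 and 2 by limma with Benjamini-Hochberg adjustment. Of 12 B and plasma cell genes 10 were higher (median 2.02, adjusted p = 0.144 with an estimated correlation) and of 14 genes of MHC class II presentation 11 were higher (median 1.92, adjusted p = 0.144 with an estimated correlation). A minority of the genes of some other cell types differed too. List medians were 1.13 for macrophages and dendritic cells, 0.67 for T and intraepithelial lymphocytes, 0.97 for Paneth cells and −0.63 for stem cells. Among their members 3 of 11, 2 of 11 and 3 of 15 were higher and 3 of 12 lower. None of these lists was past camera with an estimated correlation (adjusted p = 0.332, 0.332, 0.332 and 0.548). Genes named after their values were seen were Cd79b (4.00), the B cell chemokine Cxcl13 (4.17), Cd79a (3.94), Ms4a1 (3.35) and the complement receptor Cr2 (1.84). In the same division 11 of 38 fatty acid oxidation genes and 10 of 51 xenobiotic genes were lower in 1 and 2 (adjusted p = 0.737 and 0.548 with an estimated correlation). The labels give no batch.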
